A study of Arabidopsis thaliana with 4 samples.

How the data were processed

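Total RNA of Arabidopsis rosette leaves and whole seedlings was made into stranded libraries depleted of ribosomal RNA, per the labels' protocols, from wild type and from the mutant of TRIC1 and TRIC2 (dko). Each of the 4 groups is stated to hold 3 replicates, and the labels do not say whether these were separate plants or pools, so the p-values measure only the spread between these samples, which may be technical. Bowtie2, TopHat2, Cufflinks and Cuffdiff, each given as version 2.2.0, were used on the TAIR10 genome, per the submitters' processing notes. The annotation, the library normalization setting of Cuffdiff, the use of strand and the treatment of reads that match several places are not given in the sources used here.

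The authors deposited 2 tables, 1 per tissue, each with 34133 loci and 14 columns whose names are those of Cuffdiff's gene comparison. FPKM (fragments per kilobase of transcript, scaled to the number of fragments) was deposited by the authors as 1 value per group, pooled over its replicates and scaled within the table, per the file headers. The log2 ratio deposited by the authors is that of dko over wild type, and recomputing it from the FPKM gave a largest gap of 1.39e-05. Cuffdiff's test score per locus was deposited by the authors and is not printed here. The p-value and q-value are the authors' deposited Cuffdiff results, with a smallest p-value of 5e-05, and the q-value could be recomputed as a Benjamini-Hochberg adjustment over the tested loci (largest gap 5.24e-07). Loci past q 0.05 were the same as those the authors marked as significant, with 0 differences in both tables. Loci that the tables mark as holding too many fragments (7 in rosettes and 5 in seedlings, among them psbA and rbcL) or as not tested (15788 and 14381) have no test.

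No replicate values or counts were at hand, so the planned tests per replicate were not run, the authors' q-value was used, and no standard deviation is given. Columns of the tables left without a meaning numbered 0. The low FPKM values lie on no common steps, whole reads could not be recovered, and the depth per sample is unknown. A value of exactly 0 can be a failed estimate in such tables, for which reason loci are described as listed at 0, with no fold. Comparisons were made within a table only, as the tables were normalised separately; across tissues, calls and ratios were set side by side.

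Counts of loci past q 0.05 were taken per direction. Gene lists (20 lists with 390 entries, the targeted genes included) were fixed before the data were examined; all 390 loci were in the table and the reference. Other lists were all mitochondrial loci (146), all chloroplast loci (133) and their gene classes, and, from reference descriptions, aminoacyl-tRNA synthetases, mitochondrial and other ribosomal proteins and pentatricopeptide repeat proteins. For each list the median log2 ratio of tested members was set against 10000 random lists of the same size, drawn with replacement from tested loci matched on 10 bins of mean FPKM, and its percentile is a description of these pooled values. Calls adjusted over the list alone are a Benjamini-Hochberg adjustment of the deposited p-values of its members at 0.05. The overlap of calls between tissues was compared with independent lists, with Fisher's exact test over loci, and with 10000 draws matched on mean FPKM.

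The genes named per tissue are both targeted genes, the 10 highest and 10 lowest log2 ratios past q 0.05 with both groups above 0 and the higher at 1 FPKM or more, up to 4 members of each list past q 0.05 with the largest absolute ratios, and the 3 of highest value listed at 0 in a group. Over both tissues they are the 10 with the largest smaller ratio in the same direction, up to 5 in opposite directions, and the 3 loci on each side of each targeted gene. Transposon and tRNA loci were left out of the ranked genes. Genes outside this rule are named as such, except psbA and rbcL above, given as examples of loci without a test.

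Names come from the TAIR10.1 annotation of NCBI, which holds 31510 of the 34133 loci, and from the fixed lists. Starts in the tables count from 0: after adding 1, 11505 starts equalled those of the reference, against 135 without. Coordinates are those of the tables, 1-based, where overlapping loci share a span. Chloroplast loci were named by exact coordinates (112 of 133). The mitochondrial sequence of the reference differs from that of the tables, so mitochondrial loci were named only where a span of 300 bp or more was unique in both (15 of 146), and no coordinates were converted. Too few mitochondrial ribosomal protein genes could be named and tested to give that class a median.

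Alternatives planned before the data were examined were q thresholds of 0.01 and 0.1, a 2-fold minimum, 1 FPKM or more, q recomputed, organelle-encoded loci left out, ratios recentred on their median, and log2 ratios with a pseudocount of 1 or 0.1. A further alternative, leaving out loci with a span under 300 bp, was added later.

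The list and overlap calculations were tested on simulated data with known answers. With 200 of 18302 rosette loci changed in a simulation with a log2 spread of 0.3, 100% of the changes of log2 size 2 and 45.0% of those of log2 size 1 were recovered, and 3.33% of the calls were false. For 19718 seedling loci the values were 99.0%, 44.0% and 7.14%. These shares follow from the chosen spread and do not describe the power or the error of the deposited Cuffdiff calls. Of 200 unshifted lists of 30 genes, 5.5% in rosettes and 6.5% in seedlings lay outside percentiles 2.5 to 97.5, and 100% of the lists shifted by 0.5 lay above them in both. The simulated loci varied independently and their lists were drawn at random. These shares check the calculation only. They do not show how the percentiles behave for real lists, whose members can change together or share reads. For genes higher in both tissues, 100 simulations of independent calls over 17890 loci gave a mean overlap of 121.6, against 122.3 from the formula. With 100 shared genes planted, the mean excess over the formula was 82.9. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.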

Results

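The transcriptome of Arabidopsis thaliana wild type (accession Col-0) was compared with that of a mutant labelled as a knockout of both TRIC1 (AT3G49560) and TRIC2 (AT5G24650), called the dko here. Both genes encode proteins of the family to which the Tim17, Tim22 and Tim23 subunits of the mitochondrial import machinery belong, and they have been linked to the import of tRNA into mitochondria. RNA sequencing of total RNA depleted of ribosomal RNA was done on rosette leaves at 4 weeks and on whole seedlings at 2 weeks. All plants were grown at 22 °C with a 16 h photoperiod. Plants used for rosettes were moved to soil on day 5, and no such move is given for seedlings. The 4 groups were wild-type rosettes, dko rosettes, wild-type seedlings and dko seedlings, each stated to hold 3 replicates. The authors deposited 1 table per tissue, with 1 pooled FPKM per locus and group, so no value below has a standard deviation of its own. The error of each comparison is carried by the q-value of Cuffdiff in those tables, and sequencing depth is unknown. The design text also names high and low light, which were not analysed here.

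The targeted genes were examined first, to see whether the groups carried the mutation their labels state. In the authors' deposited tables TRIC1 fell from 34.7 to 10.7 FPKM in dko rosettes (log2 ratio -1.70, q = 0.000899) and from 33.9 to 16.2 FPKM in dko seedlings (log2 ratio -1.06, q = 0.000768). The TRIC1 transcript signal left in the dko was thus 30.7% of wild type in rosettes and 47.9% in seedlings. TRIC2 fell in seedlings from 17.7 to 0.366 FPKM in the authors' deposited table (log2 ratio -5.59, q = 0.000768). For rosettes the authors' deposited table lists TRIC2 at 17.5 FPKM in wild type and 0.069 FPKM in the dko, a log2 ratio of -7.99 with q = 0.146, which is not past the threshold of 0.05. The dko value was 0.394% of that of wild type. With q adjusted over the list alone, both targeted genes passed in each tissue (2 of 2 lower). TRIC1 lies on chromosome 3 at 18370564 to 18372139 and TRIC2 on chromosome 5 at 8437085 to 8439104, in the TAIR10 coordinates of the tables. Each is a protein-coding gene on the plus strand with 6 exons in its first annotated transcript. The position of the insertions within these genes is not given in the sources used here, so it is not known which part of the TRIC1 transcript the remaining signal covers.

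Among the 3 loci on each side of the targeted genes, the LSU genes, which respond to low sulfur supply, fell in rosettes. LSU3 and LSU1 lie next to TRIC1, and LSU4 and LSU2 next to TRIC2. The authors' deposited rosette table gives log2 ratios of -3.45 for LSU3 (q = 0.0143), -2.40 for LSU1 (q = 0.000899), -2.15 for LSU4 (q = 0.00692) and -1.19 for LSU2 (q = 0.00348). In the authors' deposited seedling table the log2 ratios of LSU3, LSU1, LSU4 and LSU2 were 0.56, -0.36, -0.77 and 0.29, and the smallest q was 0.276. AT5G24640, the locus just before TRIC2, rose in rosettes by a log2 ratio of 3.96 to 10.9 FPKM in the authors' deposited table (q = 0.006005), and EMB2820 rose in seedlings by a log2 ratio of 0.36 (q = 0.0332). The other loci beside the targeted genes, among them ATG13 and BIN4, did not pass the threshold in either of the authors' deposited tables.

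**Figure D1:**
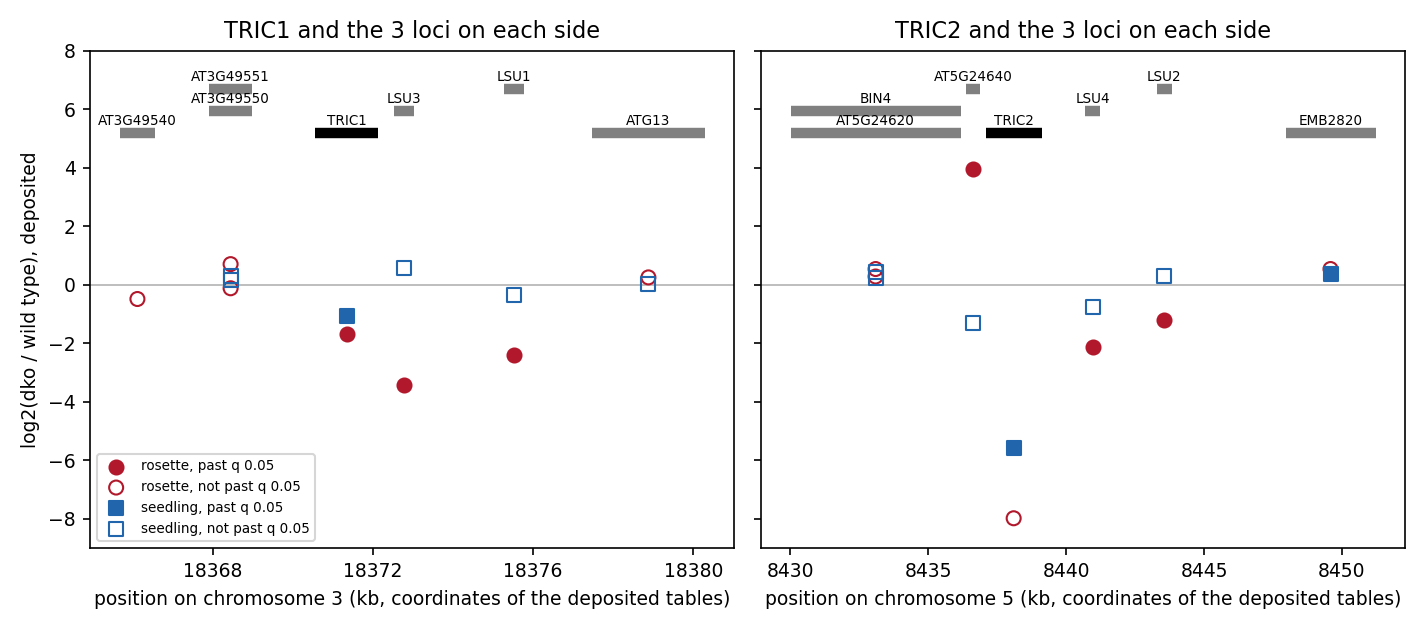
Deposited log2 ratios (dko over wild type, vertical axis) of TRIC1, TRIC2 and the 3 loci on each side, at their position in kb; bars at the top are the spans in the tables, where overlapping loci share a span, and filled symbols passed q 0.05. TRIC2 reached -7.99 in rosettes and -5.59 in seedlings, and a locus listed at 0 in the dko (AT3G49540, seedlings) has no point.

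In rosette leaves, most nuclear photosynthesis genes and part of the genes of salicylic acid defence, flavonoid synthesis, cold response and phosphate starvation fell in the dko, while 41 of 76 mitochondria-encoded loci and some genes of mitochondrial stress, plant defensins and heat shock rose. The largest rise among genes detected in both groups was that of GSTU8, a glutathione transferase, from 0.444 to 46.7 FPKM in the authors' deposited table (105-fold, q = 0.000899). UPOX, a marker of oxidative stress located in mitochondria, went from 4.81 to 173 FPKM (36.0-fold, q = 0.000899), and the mitochondrial small heat shock protein HSP23.5 from 0.260 to 9.59 FPKM (36.9-fold, q = 0.00551), both in the authors' deposited table. WRKY38 and NIMIN1, which act in salicylic acid signalling, fell from 15.9 to 0.246 FPKM (q = 0.00291) and from 18.5 to 0.457 FPKM (q = 0.00504) in the same authors' deposited table. Of 18338 loci tested, 3072 (16.8%) passed q 0.05 in the authors' deposited rosette table, 1433 higher and 1639 lower in the dko. The median absolute log2 ratio of the loci that passed was 1.06, and 727 were at least 2-fold higher and 982 at least 2-fold lower.

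Other genes with the largest rises in the authors' deposited rosette table were the defensin gene PDF1.3 (77.3-fold), the MATE efflux gene AT2G04050 (57.7-fold), the cysteine proteinase gene CP1 (48.9-fold) and ANAC087, a NAC transcription factor (43.6-fold). AT2G18193, a P-loop nucleoside triphosphate hydrolase (35.0-fold), AT5G47330, an alpha/beta-hydrolase (21.5-fold), and PDF1.2C (19.3-fold) completed the 10 largest rises in that authors' deposited table. The largest falls, beside WRKY38 and NIMIN1, included AT4G19430 (72.1-fold), AT1G80130 (34.9-fold), AT5G22460 (29.4-fold), AT2G10940 (26.8-fold), NUDT24 (24.3-fold) and the terpene synthase gene TPS04 (23.2-fold), per the authors' deposited table. The 10 largest falls also held 2 ribosomal RNA loci. AT3G41768, an 18S rRNA locus, went from 1426 to 8.41 FPKM (q = 0.000899) and the chloroplast 16S rRNA locus rrn16S from 1274 to 37.5 FPKM (q = 0.00551) in the authors' deposited rosette table. As the libraries were depleted of ribosomal RNA, these values measure what depletion left. AT2G34030 and the microRNA locus MIR171b are listed at 0 in wild-type rosettes and at 15.71 and 55.1 FPKM in dko rosettes, and HTA4, a histone H2A gene, at 9.09 FPKM in wild type and 0 in the dko, all past q 0.05 in the authors' deposited table.

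Of 45 tested members of their list, 29 nuclear photosynthesis genes fell past q 0.05 in rosettes, none rose and 16 did not pass (33 fell with q adjusted over the list alone), and the median log2 ratio was -0.93, below all 10000 random lists matched on FPKM. LHCB2.3, LHCB1.2, LHCB3 and LHCB2.2, light-harvesting proteins of photosystem II, fell by log2 ratios of -4.45, -2.54, -2.50 and -2.27 in the authors' deposited table, each with q = 0.000899. Near-identical copies such as the LHCB1 genes can share reads, and how these were assigned is not given in the sources used here.

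Among mitochondrial stress and alternative respiration genes, 5 of 16 tested rose in rosettes and 1 fell (5 and 2 adjusted over the list alone). Besides HSP23.5 and UPOX, the transcription factor gene NAC013 rose 4.67-fold and AOX1A, the stress-inducible alternative oxidase, 2.65-fold in the authors' deposited table, each with q = 0.000899. The list median of 0.18 lay at percentile 87.4 of the random lists (0.28 with a pseudocount of 1 and 0.50 with 0.1), and 10 members did not pass the test. Of 34 genes of mitochondrial protein import and its relatives, 6 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.35, above all 10000 random lists. TIM22 (3.98-fold), TIM17-1 (3.32-fold) and OM64 (1.99-fold) rose and OEP16-1 fell from 304 to 138 FPKM in the authors' deposited table. None of the 32 nuclear-encoded respiratory chain genes passed q 0.05, nor any adjusted over the list alone, and their median was 0.04, at percentile 70.0.

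The salicylic acid and pathogen defence list held 14 genes that fell and none that rose among 32 tested (18 and 2 adjusted over the list alone), with a median of -0.76, below all 10000 random lists. GRX480 fell 13.1-fold (q = 0.00231) and PR1, the classical marker of salicylic acid signalling, 4.93-fold from 11.5 to 2.33 FPKM (q = 0.000899) in the authors' deposited table. In the jasmonate, wounding and ethylene list, 4 genes rose and 4 fell among 29 (5 and 7 adjusted over the list alone). The 4 that rose were all plant defensin genes: beside PDF1.3 and PDF1.2C, PDF1.2 went from 158 to 2185 FPKM and PDF1.2B from 33.5 to 463 FPKM, each with q = 0.000899 in the authors' deposited table. This list had a median of -0.31, at percentile 0.39, and a mean of 0.30, so the median and the mean differ in sign. The copies of PDF1.2 are close relatives whose reads can be shared.

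Flavonoid and anthocyanin genes fell in 5 of 12 cases with no rise (6 and 1 adjusted over the list alone), with a median of -1.76, below all 10000 random lists (-0.86 with a pseudocount of 1). UF3GT fell 10.2-fold (q = 0.017), CHS, which encodes the entry enzyme of the pathway, 6.79-fold (q = 0.00164) and DFR 4.63-fold (q = 0.0125) in the authors' deposited table, from wild-type values of at most 1.88 FPKM. Cold, dehydration and abscisic acid genes fell in 7 of 16 cases with no rise (7 and 0 adjusted over the list alone), with a median of -0.57 at percentile 0.01. COR15A went from 589 to 112 FPKM and RD29A from 57.4 to 17.3 FPKM in the authors' deposited table, each with q = 0.000899. Phosphate starvation genes fell in 5 of 9 cases with no rise (7 and 0 adjusted over the list alone), with a median of -1.07 at percentile 0.04 (-0.70 with a pseudocount of 1). The non-coding RNAs AT4 and IPS1 fell 8.53-fold (q = 0.000899) and 8.93-fold (q = 0.0359), and the galactolipid synthase gene MGD3 fell from 12.4 to 2.38 FPKM (q = 0.000899) in the authors' deposited table. Of 5 sulfur starvation genes 3 fell (3 adjusted over the list alone), LSU1, LSU2 and SDI1, the last by a log2 ratio of -1.18 (q = 0.00231) in the authors' deposited table, and the list median was -1.18 at percentile 0.02. LSU1 and LSU2 lie next to the targeted genes, and of the 3 members elsewhere SDI2 and APR3, the latter outside the rule for named genes, did not pass, with log2 ratios of -0.24 and -0.49 in the authors' deposited table. Of 10 iron homeostasis genes 3 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.24 at percentile 5.79. IMA2 and IMA1, small peptides that promote iron uptake, fell 3.86-fold (q = 0.0167) and 2.61-fold (q = 0.0359), while the transcription factor gene BHLH101 rose 1.90-fold (q = 0.0459) in the authors' deposited table.

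Heat shock genes rose in 4 of 10 cases with no fall (5 and 0 adjusted over the list alone), with a median of 0.83 at percentile 99.9 (0.42 with a pseudocount of 1 and 0.44 for members at 1 FPKM or more). HSP70 went from 5.18 to 40.6 FPKM and HSP90.1 from 7.02 to 16.4 FPKM, each with q = 0.000899 in the authors' deposited table. Among genes of reactive oxygen and glutathione transferases, 7 rose and 3 fell of 18 (8 and 3 adjusted over the list alone), with a median of 0.32 at percentile 99.5. The kinase gene OXI1 (11.2-fold), GSTU24 (6.499-fold), and the superoxide dismutase genes FSD2 (2.85-fold) and CSD2 (2.21-fold) rose in the authors' deposited table, each with q = 0.000899. In the cell cycle list 5 of 8 tested genes fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -1.46 at percentile 1.17 (-0.57 with a pseudocount of 1). CYCB1;2, CDKB2;1 and MCM2 fell by log2 ratios of -2.48, -2.08 and -1.99, from wild-type values of 0.763 to 1.73 FPKM, whereas CYCB1;1, a cyclin gene that also responds to DNA damage, rose from 0.196 to 1.75 FPKM (q = 0.00455) in the authors' deposited table. Of 12 senescence genes 3 rose and none fell (3 and 0 adjusted over the list alone), with a median of 0.05 at percentile 62.1. DIN6, an asparagine synthase gene, rose 2.57-fold, BCB 2.39-fold and WRKY6 1.52-fold in the authors' deposited table.

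Most mitochondria-encoded loci that passed the test were higher in dko rosettes. Of 76 tested, 41 rose and 2 fell (51 and 4 adjusted over the list alone), with a median log2 ratio of 0.93, above all 10000 random lists. The cytochrome c maturation gene ccmFN1 rose 5.31-fold (q = 0.00164), ccmB 2.11-fold (q = 0.000899) and nad9, a subunit of complex I, 2.31-fold (q = 0.000899) in the authors' deposited table. Of the mitochondria-encoded respiratory chain, 1 of 6 genes rose (2 adjusted over the list alone; median 0.65, percentile 99.5), and of cytochrome c maturation 2 of 3 rose (2 adjusted over the list alone; median 1.08, percentile 99.5). The mitochondrial 18S rRNA gene rrn18 fell from 710 to 65.3 FPKM (q = 0.000899) in the authors' deposited table. This was the same direction as that of the tested rRNA loci of the nucleus and chloroplast.

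Chloroplast-encoded loci rose in 25 and fell in 5 of 89 cases in rosettes (26 and 6 adjusted over the list alone), with a median of 0.49, above all 10000 random lists. Most of the rises were of ribosomal protein genes, with 15 of 23 higher and 1 lower (15 and 1 adjusted over the list alone) and a median of 0.85, above all 10000 random lists. In the authors' deposited table rps15 rose 2.43-fold and rpl20 2.24-fold, each with q = 0.000899. Of the 4 genes of the plastid-encoded RNA polymerase, rpoC2 and rpoA rose (3 adjusted over the list alone; median 0.83, percentile 99.8), by 2.04-fold (q = 0.00818) and 2.01-fold (q = 0.0128) in the authors' deposited table. Of 15 photosystem genes 1 fell (1 adjusted over the list alone), psbN, against a mean of 1.52 falls in random lists, and their median was -0.16 at percentile 20.4. No gene of the NDH complex or the ATP synthase passed, out of 8 and 4 tested and also over each list alone, with medians of 0.49 (percentile 99.4) and -0.14 (percentile 33.5). Of 6 cytochrome b6f genes petG rose (1 adjusted over the list alone, median 0.22, percentile 88.5). Of 4 tRNA loci trnK rose (1 adjusted over the list alone, median 0.50, percentile 94.96), and this tRNA median was larger with either pseudocount. Both tested chloroplast rRNA loci fell (2 adjusted over the list alone; median -4.33, below all 10000 random lists), with rrn23S going from 1249 to 105 FPKM (q = 0.00291) in the authors' deposited table. Organelle-encoded loci carried 64.9% of the summed FPKM in wild-type rosettes and 66.4% in dko rosettes. Chloroplast loci marked as holding too many fragments, psbA and rbcL among them, enter these sums at 0 in wild type, and some have a value in the dko. The shares are therefore not sums over the same loci and do not measure organelle content.

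**Figure D2:**
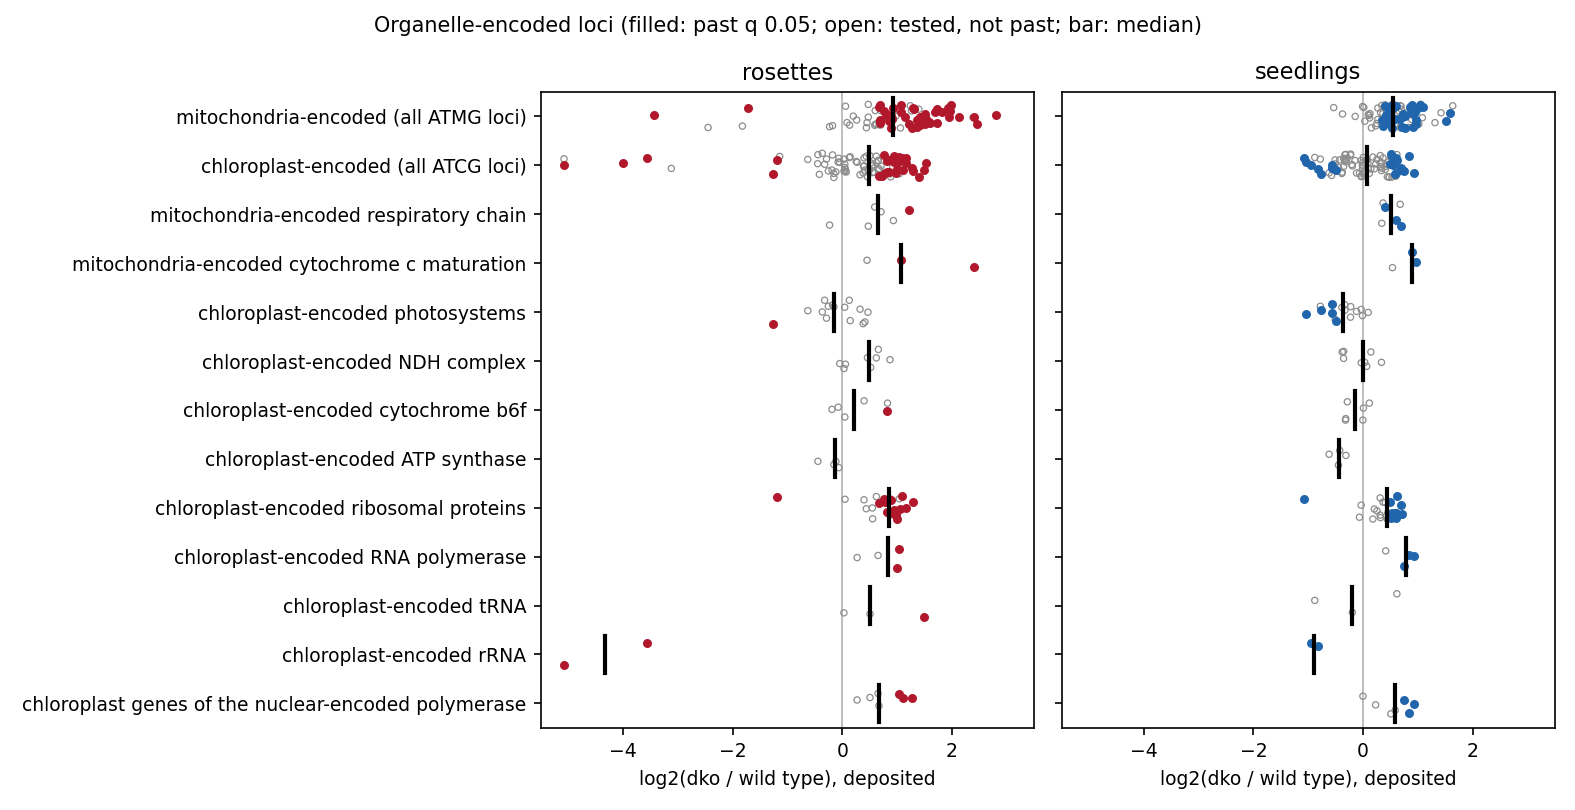
Deposited log2 ratios (dko over wild type, horizontal axis) of organelle-encoded loci in rosettes and seedlings, by class; each point is a tested locus, filled points passed q 0.05 and the black bar is the class median. The mitochondria-encoded median was 0.93 in rosettes and 0.55 in seedlings, and the chloroplast rRNA median was -4.33 in rosettes and -0.89 in seedlings, where rrn4.5S is listed at 0 in wild type and has no point.

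In seedlings, most photosynthesis genes and part of the genes of cold and abscisic acid response, senescence, iron homeostasis and phosphate starvation fell, while 35 of 78 mitochondria-encoded loci, 7 of 15 mitochondrial stress genes and 9 of 34 import genes rose. PORA, a protochlorophyllide reductase, fell from 10.1 to 0.167 FPKM (60.3-fold, q = 0.000768) and RBCS2B, a small subunit of Rubisco, from 1760 to 165 FPKM (10.7-fold, q = 0.000768) in the authors' deposited table. DIN6 fell from 62.0 to 6.15 FPKM (10.1-fold, q = 0.000768) in the same authors' deposited table. ACC2, the plastid-targeted homomeric acetyl-CoA carboxylase, rose from 3.71 to 22.0 FPKM (5.92-fold, q = 0.000768) in the authors' deposited seedling table. Of 19747 loci tested, 3267 (16.5%) passed q 0.05 in the authors' deposited table, 1659 higher and 1608 lower in the dko. The median absolute log2 ratio of the loci that passed was 0.63, and 243 were at least 2-fold higher and 342 at least 2-fold lower.

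Further large rises in the authors' deposited seedling table were those of AT5G60260 (7.45-fold), AT5G53240 (7.02-fold), the glycosyl hydrolase gene AT5G66150 (6.71-fold), the F-box gene AT2G24255 (5.72-fold), AT4G05370 (5.69-fold) and AT1G30170 (5.595-fold). AT2G35570 (5.23-fold), AT3G12410 (4.97-fold) and AT2G04050 (4.94-fold) completed the 10 largest in that authors' deposited table. The largest falls, beside PORA, TRIC2, RBCS2B and DIN6, were AT2G14247 (28.5-fold), AT1G14250, a nucleoside phosphatase gene (11.7-fold), the glutaredoxin gene AT3G21460 (9.997-fold), AT2G30766 (9.76-fold), AT3G62950 (9.60-fold) and AT4G13495 (7.93-fold), per the authors' deposited table. HTA4 and AT4G13572 are listed at 0 in dko seedlings and at 7.54 and 5.07 FPKM in wild type, and the chloroplast rrn4.5S locus at 0 in wild type and 149 FPKM in the dko, past q 0.05 in the authors' deposited table.

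Of 46 photosynthesis genes, 41 fell in seedlings, none rose and 5 did not pass (45 fell adjusted over the list alone), with a median log2 ratio of -1.14, below all 10000 random lists. LHCB2.3 went from 572 to 88.4 FPKM and LHCB1.4 from 2806 to 443 FPKM in the authors' deposited table, each with q = 0.000768. Mitochondrial stress genes rose in 7 of 15 cases and fell in 1 (8 and 1 adjusted over the list alone), with a median of 0.37 at percentile 99.9. AOX1C rose 4.03-fold (q = 0.00141), and UPOX, HSP23.5 and NAC013 rose 3.37-fold, 3.25-fold and 2.00-fold, each with q = 0.000768 in the authors' deposited table. Import genes rose in 9 of 34 cases and fell in 1 (11 and 1 adjusted over the list alone), with a median of 0.21 at percentile 99.98. TIM17-1 (2.19-fold), TIM22 (1.84-fold), OM64 (1.80-fold) and TOM6 (1.54-fold) rose in the authors' deposited table. Of the 32 nuclear-encoded respiratory chain genes 3 rose (1 adjusted over the list alone), PSST by 1.35-fold, ATPB3 by 1.29-fold and SDH1-1 by 1.27-fold in the authors' deposited table, and the median was 0.15 at percentile 99.6. These 3 rises and 0 falls compare with means of 3.12 and 5.21 in random lists.

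Among defence genes in seedlings, ACD6, NIMIN1 and several defensin genes fell and PR2 rose. In the salicylic acid list 8 of 30 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.20 at percentile 0.15. ACD6 fell 4.49-fold and NIMIN1 2.80-fold, while PR2, a glucanase gene, rose 1.67-fold, each with q = 0.000768 in the authors' deposited table. In the jasmonate list 9 of 28 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -0.21 at percentile 0.31. PDF1.3, PDF1.2 and PDF1.2C fell 5.94-fold (q = 0.0157), 3.85-fold (q = 0.000768) and 3.41-fold (q = 0.0036), and ORA59, an ethylene response factor gene, 1.81-fold (q = 0.00847) in the authors' deposited table. Of 15 flavonoid genes 1 fell (0 adjusted over the list alone), PAL1 by 1.299-fold (q = 0.0281) in the authors' deposited table, with a median of -0.25 at percentile 0.60. Random lists matched to the flavonoid genes held a mean of 0.87 falls. DREB2A fell 2.17-fold (q = 0.000768 in the authors' deposited table) as the sole call among 9 heat shock genes (1 adjusted over the list alone; median -0.12, percentile 16.6). In the reactive oxygen list 3 of 19 rose and 2 fell (3 and 3 adjusted over the list alone; median 0.08, percentile 84.8), with FSD2 up 1.88-fold and GSTU24 down 2.32-fold in the authors' deposited table, each with q = 0.000768. The matched random lists held means of 1.73 rises and 2.55 falls.

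Cold, dehydration and abscisic acid genes fell in 11 of 17 cases in seedlings with no rise (13 and 0 adjusted over the list alone), with a median of -0.52, below all 10000 random lists. CBF1, a transcription factor gene of cold acclimation, fell 3.31-fold and COR47 2.36-fold, each with q = 0.000768 in the authors' deposited table. Senescence genes fell in 7 of 14 cases with no rise (7 and 0 adjusted over the list alone), with a median of -0.41 at percentile 0.02. SEN1 and RNS1 fell 4.58-fold and 4.34-fold, each with q = 0.000768 in the authors' deposited table. Iron homeostasis genes fell in 5 of 12 cases with no rise (6 and 1 adjusted over the list alone), with a median of -1.40, below all 10000 random lists. BHLH101 fell 7.20-fold (q = 0.00547), IMA2 7.09-fold (q = 0.00202) and FRO3, a ferric reductase gene, 2.04-fold (q = 0.000768) in the authors' deposited table. Of 10 phosphate starvation genes 5 fell and none rose (7 and 0 adjusted over the list alone), with a median of -0.40 at percentile 0.03, and MGD3 fell 2.33-fold (q = 0.000768) in the authors' deposited table. Among 5 sulfur starvation genes SDI2 rose 1.70-fold (q = 0.000768 in the authors' deposited table) and the others did not pass (1 adjusted over the list alone; median 0.26, percentile 96.0). CYCB1;1 rose 2.07-fold (q = 0.000768 in the authors' deposited table) as the sole call among 12 cell cycle genes (1 adjusted over the list alone; median 0.12, percentile 85.0). The matched random lists held a mean of 0.96 rises.

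**Figure D3:**
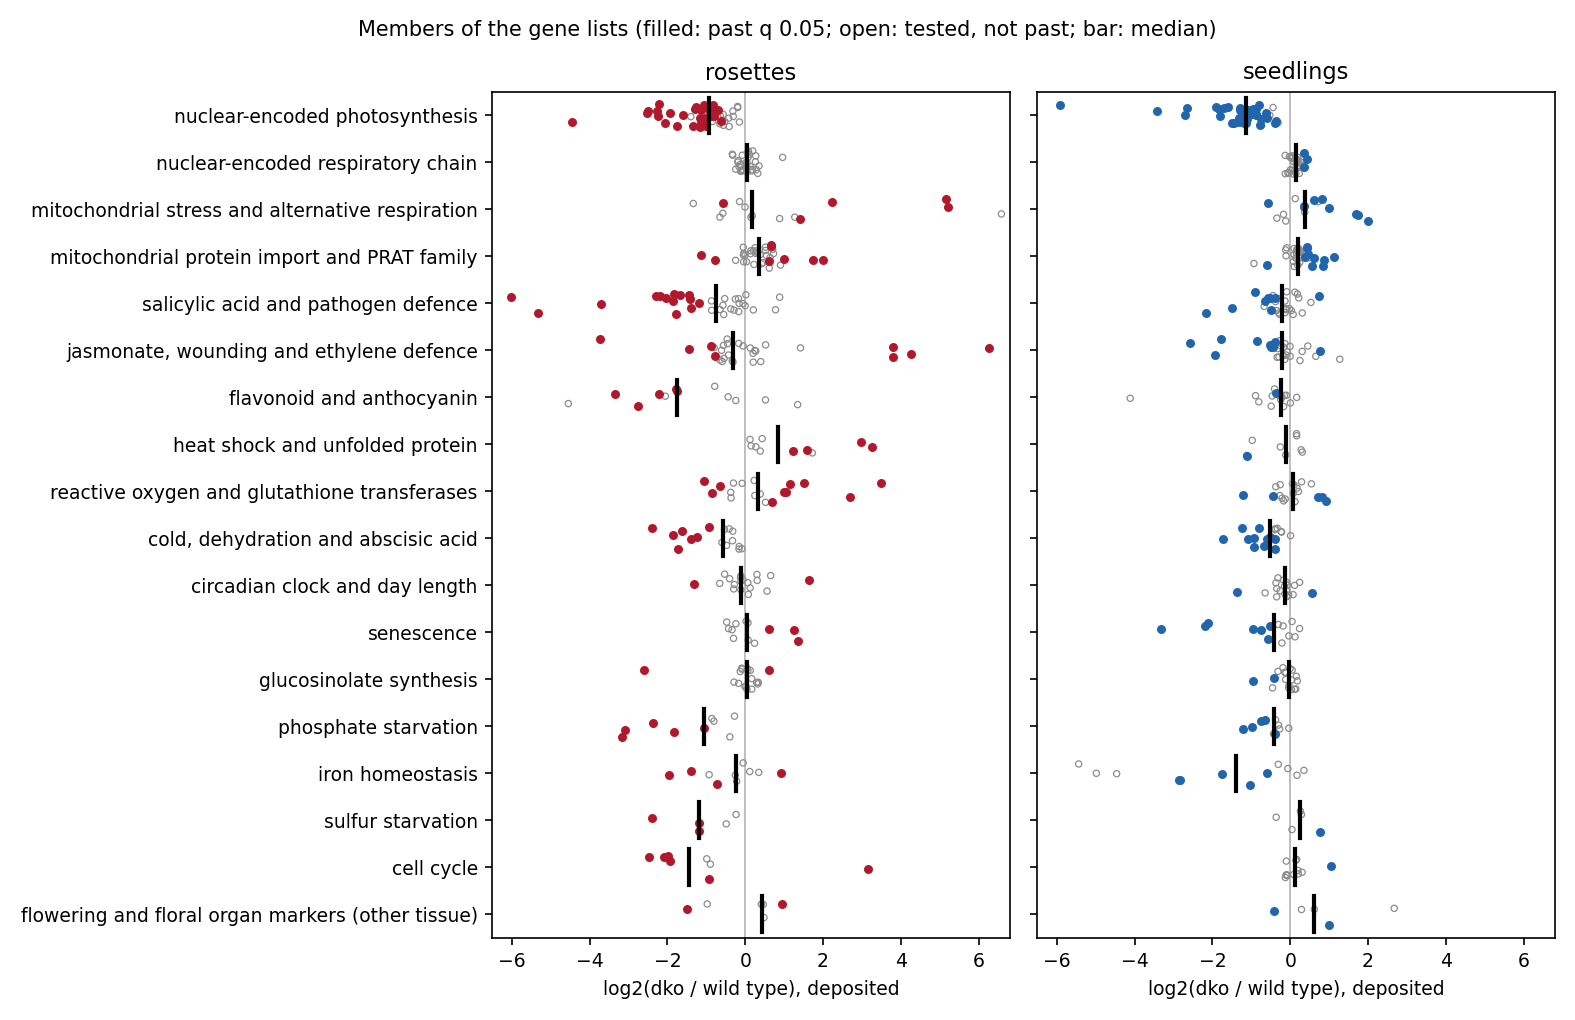
Deposited log2 ratios (dko over wild type, horizontal axis) of the members of 18 gene lists fixed before the data were examined, in rosettes and seedlings; filled points passed q 0.05, open points were tested and did not, and the black bar is the list median. The photosynthesis medians were -0.93 and -1.14, and those of the nuclear-encoded respiratory chain 0.04 and 0.15.

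Mitochondria-encoded loci rose in 35 of 78 cases in seedlings and none fell (42 and 0 adjusted over the list alone), with a median of 0.55, above all 10000 random lists. In the authors' deposited table ccmFN2 rose 1.97-fold and ccmB 1.85-fold, each with q = 0.000768, nad1 1.62-fold (q = 0.00968) and atp1 1.52-fold (q = 0.013). Of the mitochondria-encoded respiratory chain 3 of 6 genes rose (4 adjusted over the list alone; median 0.51, percentile 99.7), and of cytochrome c maturation 2 of 3 (3 adjusted over the list alone; median 0.89, percentile 99.96). The rRNA gene rrn18 rose in seedlings from 63.2 to 107 FPKM (q = 0.000768), while the chloroplast loci rrn16S and rrn23S fell from 111 to 57.2 and from 203 to 114 FPKM (each q = 0.000768) in the authors' deposited table. Chloroplast rRNA loci thus held 2 falls and, with rrn4.5S, 1 rise among 3 (2 and 1 adjusted over the list alone; median -0.89, percentile 2.05).

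Chloroplast-encoded loci rose in 14 and fell in 8 of 88 cases in seedlings (20 and 8 adjusted over the list alone), with a median of 0.06 at percentile 97.47. Ribosomal protein genes rose in 9 of 23 cases and fell in 1 (13 and 1 adjusted over the list alone), with a median of 0.44, above all 10000 random lists, and rpoC2, rpoB and rpoC1 rose among 4 polymerase genes (3 adjusted over the list alone; median 0.79, percentile 99.99). The authors' deposited table gives 1.91-fold (q = 0.00141), 1.80-fold (q = 0.000768) and 1.67-fold (q = 0.00202) for rpoC2, rpoB and rpoC1. Of 16 photosystem genes 5 fell and none rose (5 and 0 adjusted over the list alone), with a median of -0.36 at percentile 0.60, and psbN and psbJ fell 2.05-fold and 1.49-fold (each q = 0.000768) in the authors' deposited table. No gene passed among 8 of the NDH complex, 6 of cytochrome b6f, 4 of the ATP synthase and 3 tRNA loci, also over each list alone, with medians of -0.00015 (percentile 59.3), -0.14 (percentile 27.9), -0.44 (percentile 5.17) and -0.19 (percentile 27.1).

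The tissues were then compared, to see whether the same genes changed in leaves and seedlings. AT1G14250, PCC1, LHCB2.3, AT5G03350, AT3G22235, GRF11 and LHCB1.4 fell, and ACC2, AT2G04050 and AT5G60250 rose, by the largest amounts common to both tissues. The authors' deposited tables give log2 ratios in rosettes and seedlings of -4.06 and -3.55 for AT1G14250, -2.89 and -2.71 for PCC1, a pathogen-responsive gene, and 2.75 and 2.57 for ACC2. The same authors' deposited tables give -4.32 and -2.48 for the lectin gene AT5G03350, -3.13 and -2.30 for GRF11, a 14-3-3 protein gene, and 4.15 and 2.28 for AT5G60250. Of 17890 loci tested in both tables, 1304 passed q 0.05 in both, and 1183 of these (90.7%) changed in the same direction. Higher in both were 725 loci, against 122 for independent lists and at most 170 in 10000 random draws matched on FPKM. Lower in both were 458, against 136 for independent lists and at most 187 in the random draws (Fisher's exact test, two-sided, over loci that are not independent replicates, p = 3.19e-139). Opposite directions were found for 121 loci, 67 higher in rosettes and lower in seedlings (121 for independent lists) and 54 the reverse (138 for independent lists). The log2 ratios had a Pearson correlation of 0.44 and a Spearman correlation of 0.44 across 17184 loci at 1 FPKM or more in both tissues, and 1017 of 1178 loci with the same direction had the larger ratio in rosettes. The tables were normalised separately and the difference between the tissues was not tested per gene. Rosettes and seedlings also differed in age (4 and 2 weeks) and in the move to soil, given for rosettes only. Ribosomal RNA left by depletion also differed more between the genotypes in rosettes. The authors' deposited log2 ratios of AT3G41768, rrn16S, rrn23S and rrn18 were -7.41, -5.09, -3.57 and -3.44 in rosettes. In seedlings they were -1.03, -0.95, -0.83 and 0.76, and rrn4.5S had no test in rosettes. Here and below, effects of tissue, age, growth on soil and library preparation cannot be told apart.

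**Figure D4:**
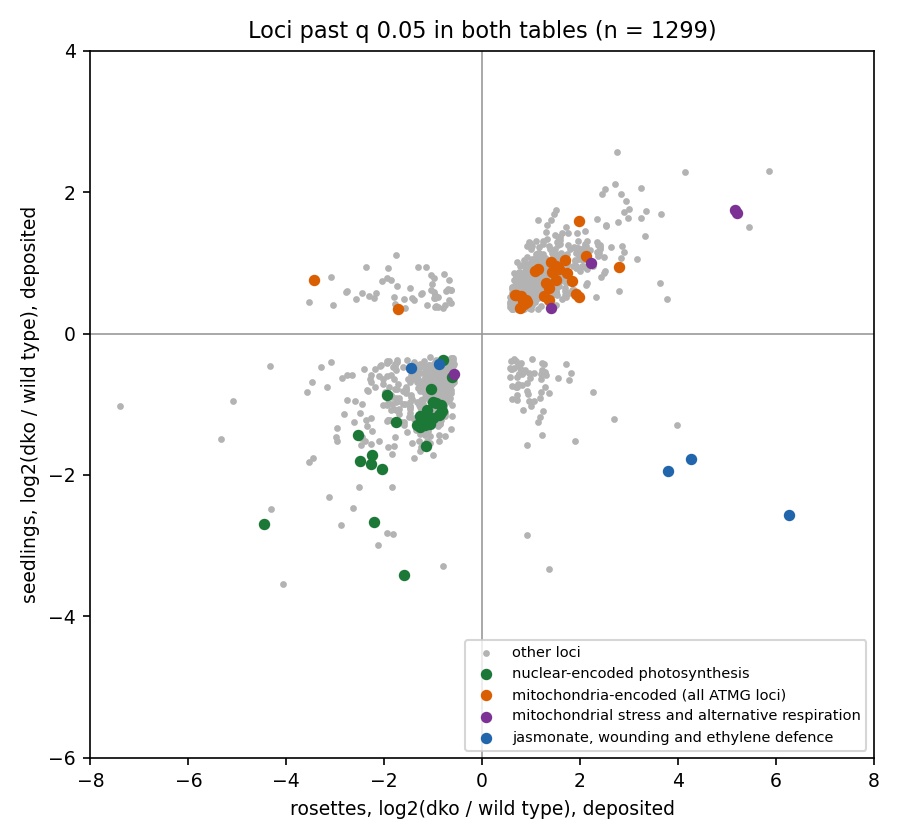
Deposited log2 ratios (dko over wild type) in rosettes (horizontal axis) and seedlings (vertical axis) of the 1299 loci past q 0.05 in both tables with a ratio in both; coloured points are members of the lists named in the key. Photosynthesis genes lie at the lower left, most mitochondria-encoded loci at the upper right, and the defensin genes PDF1.3, PDF1.2 and PDF1.2C at the lower right.

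For some lists the ratios differed between the tissues when set against random lists of the difference. The median difference, seedling minus rosette log2 ratio, was -1.15 for heat shock genes, -0.43 for mitochondria-encoded loci and -0.40 for chloroplast-encoded loci, each below all 10000 random lists, -0.46 for chloroplast ribosomal protein genes at percentile 0.01, and -0.54 for senescence genes at percentile 0.02. Among mitochondria-encoded loci it was -0.47 for those that could not be named, below all 10000 random lists, but 0.04 for those with a name (percentile 77.7) and 0.04 for the respiratory chain (percentile 71.1). It was 1.46 for cell cycle genes and 0.38 for salicylic acid defence genes, both above all 10000 random lists, 0.82 for phosphate starvation and 1.23 for sulfur starvation genes, each at percentile 99.96, and 0.78 for flavonoid genes at percentile 99.9. It was -0.41 for chloroplast-encoded photosystem genes (percentile 0.51), -0.43 for those of the NDH complex (percentile 1.42), -0.36 for iron homeostasis genes (percentile 1.1) and 0.12 for the nuclear-encoded respiratory chain (percentile 99.55). For nuclear photosynthesis genes it was -0.10 at percentile 52.2, and for cold, dehydration and abscisic acid genes 0.07 at percentile 88.3. These percentiles describe the pooled values of these groups and carry no replicate error. The cell cycle and heat shock differences rest on 8 genes each, and no pseudocount was applied to the differences. With a pseudocount of 1 the rosette list medians shrank from -1.46 to -0.57 for cell cycle and from 0.83 to 0.42 for heat shock genes. Over the 8 heat shock genes the medians were 0.41 in rosettes and -0.05 in seedlings.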

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

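The differences between the tissues given here were not tested; they are the 5 loci past q 0.05 in opposite directions with the largest smaller ratio. The plant defensin genes PDF1.3, PDF1.2C and PDF1.2 rose in dko rosettes and fell in dko seedlings. PDF1.3 had log2 ratios of 6.27 in rosettes and -2.57 in seedlings in the authors' deposited tables, a difference (seedling minus rosette) of -8.84. For PDF1.2C the ratios in the authors' deposited tables were 4.27 and -1.77, a difference of -6.04, and for PDF1.2 they were 3.79 and -1.94, a difference of -5.74. These copies can share reads, so they do not count as independent loci. DIN6, the asparagine synthase gene that responds to darkness and sugar supply, had 1.36 in rosettes and -3.33 in seedlings, a difference of -4.69, in the authors' deposited tables. DIN11, a dioxygenase gene, had 1.90 and -1.52, a difference of -3.42, at values of at most 1.25 FPKM in the authors' deposited tables. The wild-type level of DIN6 itself was 5.30 FPKM in rosettes and 62.0 FPKM in seedlings, and that of PDF1.2 was 158 and 25.1 FPKM, per the authors' deposited tables, which were normalised separately.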

How the results depend on the processing

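The alternative that left out loci with a span under 300 bp was chosen after the data were seen; the others were planned. The counts of loci past the threshold moved by over 1.5 times where the criterion itself was stricter, which by construction lets fewer loci pass. At q 0.01 there were 1783 loci in rosettes, 2040 in seedlings and 645 in the same direction in both. With a 2-fold minimum there were 1709, 585 and 243, and with ratios recentred as well 1700 (702 higher, 998 lower), 583 (236 higher, 347 lower) and 243. In seedlings the loci past q 0.05 were 1659 higher and 1608 lower, but 989 and 1051 at q 0.01 and 243 and 342 with the 2-fold minimum, so which direction held more loci changed; the cause was not tested. At q 0.1 the counts were 4073, 4167 and 1615. With 1 FPKM or more they were 3014, 3265 and 1182, with organelle-encoded loci left out 2988, 3203 and 1138, with spans of 300 bp or more 3062, 3253 and 1179, and with q recomputed 3072, 3267 and 1183. The overlap at 1 FPKM or more in both tissues was 1169. Of the list medians under a pseudocount, a minimum FPKM or recentring, 291 stayed within the 95% bootstrap range over members and 5 did not. The sole change of sign among all of these was that of the mitochondrial ribosomal proteins in rosettes, from 0.007 to -0.008 when recentred, with no member past q 0.05. The 5 were the cell cycle list in rosettes (-0.57 with a pseudocount of 1), chloroplast rRNA in seedlings (-0.83 with either pseudocount) and pentatricopeptide repeat proteins with a pseudocount of 1 (0.32 in rosettes and 0.28 in seedlings). The bootstrap ranges of short lists are wide, and other medians with an absolute value above 0.1 changed by over 1.5 times within them. With a pseudocount of 1 the rosette medians were -0.86 for flavonoid genes (-1.76 without), 0.42 for heat shock genes (0.83 without; 0.44 for members at 1 FPKM or more), -0.70 for phosphate starvation genes, 0.28 for mitochondrial stress genes (0.18 without; 0.50 with a pseudocount of 0.1), 0.28 for flowering genes, -0.22 for root markers and 0.99 for chloroplast tRNA loci (also 0.99 with a pseudocount of 0.1). In seedlings they were -0.07 for heat shock genes, 0.29 for flowering genes and -0.16 for root markers. A pseudocount of 1 draws ratios of loci near 1 FPKM towards 0, and members listed at 0 in a group enter with a pseudocount. No paired analysis was possible because the tables hold 1 pooled value per group, and for the same reason no replicate could be left out in turn. Depth limits are unknown without counts: of 37 rosette loci with at least 5 FPKM in a group and a ratio of 16-fold or more, 14 did not pass q 0.05, TRIC2 among them, and in seedlings 3 of 6.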

Other observations

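The tests on mitochondria-encoded loci and on the LSU genes, and the search for lost loci, were chosen after the results were seen; the test of chloroplast gene classes was set before its result. Some genes of pentatricopeptide repeat proteins, aminoacyl-tRNA synthetases and ribosomal proteins rose. The synthetases and the ribosomal proteins not described as mitochondrial were not split into cytosolic and organelle members. Of the pentatricopeptide repeat proteins, most of which bind organelle transcripts, 55 of 225 tested rose in rosettes and none fell (63 and 0 adjusted over the list alone), and 82 of 237 rose in seedlings and 1 fell (91 and 2 adjusted over the list alone). The median log2 ratios of 0.47 and 0.41 lay above all 10000 random lists, and the median difference, seedling minus rosette, was -0.14, below all 10000 random lists. In the authors' deposited tables EMB175 rose 2.93-fold in rosettes and 1.95-fold in seedlings, and AT2G15630 2.91-fold and 2.45-fold. Of the aminoacyl-tRNA synthetases, 4 of 51 rose and 2 fell in rosettes (4 and 2 adjusted over the list alone), and 20 of 52 rose and 2 fell in seedlings (21 and 3 adjusted over the list alone), with medians of 0.32 and 0.27, both above all 10000 random lists. The 4 rises in rosettes compare with a mean of 3.86 in random lists. AT1G17960 rose 5.68-fold in rosettes and 4.13-fold in seedlings, and OVA2 rose 1.65-fold in seedlings, per the authors' deposited tables. Of the other nuclear-encoded ribosomal proteins, 40 of 304 rose and 1 fell in rosettes (35 and 0 adjusted over the list alone), and 56 of 310 rose and 4 fell in seedlings (62 and 5 adjusted over the list alone), with medians of 0.35 and 0.23, above all 10000 random lists, and a median difference, seedling minus rosette, of -0.14 at percentile 0.595. Of 8 proteins described as mitochondrial ribosomal proteins, none passed in rosettes (median 0.01, mean -0.06 of opposite sign, percentile 48.5) and AT1G16870 and MRPL11 rose in seedlings (2 adjusted over the list alone; median 0.34, percentile 99.7).

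Of 19 clock and day length genes, LHY rose 3.09-fold and ELF4 fell 2.499-fold in rosettes, and GRP8 rose 1.47-fold and PRR9 fell 2.57-fold in seedlings in the authors' deposited tables (1 and 1 in each tissue adjusted over the list alone), with medians of -0.11 (percentile 21.3) and -0.14 (percentile 8.38). Random lists matched to the clock genes held means of 1.48 rises and 1.76 falls in rosettes, and 1.63 and 1.79 in seedlings. Of 18 glucosinolate genes, MAM3 fell in both tissues, 6.05-fold and 1.94-fold, MYB28 rose 1.54-fold in rosettes and CYP79B3 fell 1.33-fold in seedlings in the authors' deposited tables (1 and 1 in rosettes and 0 and 1 in seedlings adjusted over the list alone). The glucosinolate medians were 0.05 (percentile 65.8) and -0.04 (percentile 35.3), and in rosettes the mean of -0.06 had the opposite sign. Their random lists held means of 1.42 rises and 1.62 falls in rosettes, and 1.63 and 2.14 in seedlings. Of the markers of other tissues, none of the 3 tested root genes passed in either tissue, also over the list alone, with medians of -0.38 (percentile 21.8) and -0.26 (percentile 16.3). Of the flowering genes, FUL rose in both tissues, 1.94-fold and 1.98-fold, in the authors' deposited tables. FLC fell 2.83-fold in rosettes and SOC1 1.34-fold in seedlings in the same authors' deposited tables. In rosettes 6 and in seedlings 5 were tested, with 1 rise and 1 fall in each tissue adjusted over the list alone. The medians were 0.44 and 0.62 (percentiles 93.2 and 99.2), but 0.28 and 0.29 with a pseudocount of 1. In rosettes the flowering list's mean of -0.03 differed in sign from its median.

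Neighbouring loci on chromosome 4 had values at or near 0 in the dko in both tissues. Among 16729 loci at 1 FPKM or more in wild type in both tissues, 9 had at most 5% of the wild-type FPKM left in the dko in both, a limit set after the values were seen. By the same limit in the other direction, 10 loci at 1 FPKM or more in the dko had at most 5% of that in wild type in both tissues, among them AT4G31030, listed at 0 in wild type and at 21.1 and 24.8 FPKM in the dko in the authors' deposited tables. None of these 10 passed q 0.05 in either tissue, but most of them had no test in either and so could not pass. Among these, psaB is marked as holding too many fragments. AT4G31030 was tested in both tissues and did not pass (q = 0.452 and q = 0.475 in the authors' deposited tables). The 9 loci low in the dko included, besides TRIC2, HTA4, AT4G13572 and AT4G13575, 3 loci within positions 7884516 to 7893705 of chromosome 4. HTA4 is listed at 9.09 FPKM in wild-type rosettes and 7.54 in wild-type seedlings and at 0 in both dko groups, AT4G13572 at 5.44 and 5.07 against 0.109 and 0, and AT4G13575 at 8.01 and 14.4 against 0 and 0.0344, in the authors' deposited tables. HTA4 passed q 0.05 in both tissues, AT4G13572 in seedlings and AT4G13575 in rosettes. UNE15, on the left of these, is listed at 3.24 and 3.22 FPKM in wild type and 0.127 and 0.165 in the dko, with q = 0.482 and q = 0.369 in the authors' deposited tables. The flanking loci AT4G13550 and AT4G13590 had log2 ratios of 0.34 and -0.16 in rosettes and -0.17 and 0.05 in seedlings, none past q 0.05 in the authors' deposited tables. AT4G13575, UNE15, AT4G13550, AT4G13590, AT4G31030 and psaB are outside the rule for named genes and were chosen after their values were seen. What lies behind these values was not tested.

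Mitochondria-encoded loci had medians of 0.93 and 0.55, the first pattern weighed. A single scaling factor per library would move nuclear-encoded loci alike, whatever the centring, yet the lower quartile of the mitochondria-encoded loci lay above the median of nuclear-encoded loci at 1 FPKM or more by 0.639 in rosettes and 0.355 in seedlings, which argues against it. A larger number of mitochondria might raise nuclear-encoded respiratory chain genes by a like amount. Their upper quartiles of 0.17 and 0.21 lay below the mitochondria-encoded medians, so no rise of that size was seen in them. The list of mitochondrial protein import genes and their relatives, the plastid envelope gene OEP16-1 among them, had medians of 0.35 and 0.21. Of 34 tested, 6 rose and 2 fell in rosettes, 9 rose and 1 fell in seedlings, and most did not pass. How far nuclear transcripts follow the number of mitochondria is not known here, so a larger number stays open. Loci that could not be named had medians of 0.94 and 0.54 against 0.70 and 0.64 for named ones, but with 15 of 146 loci named the others hold ordinary genes too, so a change along the whole mitochondrial genome, in transcription, RNA stability or genome number, stays open. Reads shared with the copy of the mitochondrial genome on chromosome 2, the rRNA left by depletion, which fell in rosettes, and a direct effect of the genotype stay open and untested. In seedlings AT3G41768, rrn16S and rrn23S fell as well, by log2 ratios of -1.03, -0.95 and -0.83 in the authors' deposited table, while rrn18 and rrn4.5S rose.

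The fall of the LSU genes in rosettes involved 4 loci next to the targeted genes, with a median log2 ratio of -2.27. A local effect of the insertions that acted alike in both tissues would lower the same loci in seedlings. There their median was -0.035 and 0 of 4 passed q 0.05, which argues against such an equal effect as the whole cause. LSU3 and LSU4 had only 2.15 and 1.95 FPKM in wild-type seedlings, so their calls decide little. AT5G24640, also beside TRIC2, rose in rosettes, and a local effect that differs between the tissues stays open. If the fall belonged to a wider response to sulfur supply, listed genes elsewhere would fall as well: 1 of 3 did so in rosettes, SDI1, while SDI2 and APR3, the latter outside the rule for named genes, had log2 ratios of -0.24 and -0.49 with q = 0.601 and q = 0.474 in the authors' deposited table. With 3 genes this cannot be told apart from no such response. A difference between leaves of soil-grown plants and seedlings in sulfur supply may matter and stays untested.

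In chloroplasts, genes read wholly or partly by the nuclear-encoded polymerase (accD, clpP, ycf2 and the rpoB operon) were expected to stand apart from photosystem genes if the balance of the plastid polymerases changed. Their median lay above that of the photosystem genes by 0.82 in rosettes and 0.95 in seedlings, the direction that hypothesis predicts. The photosystem median rests on 15 tested genes in rosettes and 16 in seedlings. It leaves out loci marked as holding too many fragments, psbA and psaB among them in both tissues, so how these changed is not known. Of 7 such loci rpoC2 and both ycf2 copies rose in rosettes, and rpoC2, rpoB and rpoC1 in seedlings, with none lower (5 and 4 adjusted over the list alone) and medians of 0.67 (percentile 99.9) and 0.59 (percentile 99.95). The ycf2 copies are copies of 1 gene and share sequence, and 1 copy lies near the floor. It had 0.372 FPKM in wild-type rosettes and 0.804 in dko rosettes, against 307 and 741 for the other, in the authors' deposited table. Neither accD nor clpP, both outside the rule for named genes, passed in either tissue, and most photosystem genes did not pass in rosettes. Of 23 ribosomal protein genes 15 rose in rosettes and 9 in seedlings, so rises were not limited to the 7 loci. The ribosomal protein median was 0.85 in rosettes, above the 0.67 of the 7 loci, and 0.44 in seedlings, below their 0.59. In rosettes the contrast with photosystem genes therefore does not single out the 7 loci. In seedlings the ribosomal protein median also lay above that of the photosystem genes, which was -0.36. The authors' deposited log2 ratios of accD and clpP in seedlings were -0.0018 and 0.23, and the loci that passed there all belong to the rpoB operon. The seedling contrast therefore does not show a rise shared by the 7 loci either. An effect of the genotype, by way of the nuclear photosynthesis genes that fell, stays open and untested.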
